A study of Caenorhabditis elegans with 6 samples.

How the data were processed

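Messenger RNA levels were measured by RNA sequencing in 6 libraries of cells sorted from dissociated embryonic cultures of Caenorhabditis elegans: 2 of wild-type non-BAG cells, 2 of wild-type BAG neurons and 2 of BAG neurons of the pmk-3(wz31) mutant. Per the labels' protocols, green fluorescent cells were taken by flow cytometry with dead cells excluded by propidium iodide, RNA was column-purified, small amounts of it were amplified into libraries with a commercial whole-transcriptome kit, and paired-end reads were made on an Illumina instrument. The authors deposited 1 table of normalized counts, treated here as a signal per gene with 1 column per library and 47063 gene rows. The submitters' processing notes name STAR, HTSeq and DESeq2 without versions or roles; the genome build, the annotation release and the use of strand are not given in the sources used here, so no coordinates are printed. Within each library every deposited value was a whole multiple of 1 step, the value of 1 read, and all values came out whole within 0.01 of a read (100.0%). The recovered totals ran from 6181113 to 8596169 reads. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 50.4, 33.2 and 10.9 in non-BAG, wild-type BAG and mutant BAG. The first 2 principal components of the log2 values held 58.3% and 18.3% of the variance.

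Genes with a value of at least 10 in at least 2 libraries were tested, 14211 in all. Limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with a mean-variance trend, all 3 groups in 1 fit with 3 residual degrees of freedom and no replicate block, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Changes are on the log2(value + 1) scale and understate those of genes with low values. In the 3 comparisons the group named first is compared with the group named after it. The 39 gene lists, the tests, the alternatives below and the rule for named genes were chosen before the data were examined. Lists with at least 5 tested members, 38 of them, were tested with camera at a correlation of 0.01 and again with an estimated correlation. The Toll-like receptor pathway, with 4 tested members, was not. Named genes are pmk-3, ins-1 and the BAG identity genes, and in each comparison the 12 largest rises and 12 largest falls among protein-coding or named genes past the threshold with a mean of at least 100.0 and no overlap between the groups. For each list they are 2 to 4 members, those with the largest changes past the threshold or otherwise those with the highest means. Members of lists that did not pass are mostly left out, and the last comparison names members only for the lists it describes. Current gene names and exon overlaps came from the reference annotation, which may differ from the authors'. Named genes that share exons with genes under 10% of their own level, and are called uncertain only here, were Y57G11B.97, acr-2, ceh-37, che-7, dlk-1, exp-2, flp-17, gcy-31, gcy-33, gcy-9, glb-5, grk-2, lgc-40, mec-2, mgl-3, mig-6, rab-3, rgs-6, unc-41, unc-7, F09F7.5, acdh-2, gpb-1, irk-3, mec-12, phf-33 and ZK822.1.

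Alternatives were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, TMM and quantile scaling, the replicate number as a block, no trend, only the groups compared, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, an added minimum change of 1 log2 unit, each library left out in turn, and for lists fry, the block and, chosen after the data were seen, each library left out. A library left alone in its group was assumed to vary like the other groups. On simulated data for mutant against wild-type BAG (13522 genes), limma recovered 6.06%, 73.1% and 100.0% of genes changed by 1, 2 and 3 log2 units and called 0.0751% of unchanged genes, while edgeR recovered 6.06%, 77.6% and 100.0%.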

Results

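The transcriptomes of BAG neurons, a pair of carbon dioxide and oxygen sensing neurons in the head of the nematode Caenorhabditis elegans, were measured by RNA sequencing of sorted cells. The cells came from dissociated embryos kept in culture overnight, from animals in which the promoter of gcy-9 drives green fluorescent protein. The 6 libraries form 3 groups of 2: non-fluorescent wild-type cells (non-BAG), fluorescent wild-type cells (BAG), and fluorescent cells of animals carrying the wz31 mutation in pmk-3, which encodes a p38 MAP kinase. Per the labels the reporter does not depend on pmk-3 and most sorted cells were fluorescent on inspection. The table held 6181113 and 8514846 reads in the non-BAG libraries, 7592477 and 8596169 in the wild-type BAG libraries and 6402074 and 6456296 in the mutant BAG libraries. Ribosomal RNA genes took 15% and 10.5% of the non-BAG reads, 11.5% and 10.4% of the wild-type BAG reads and 14.1% and 14.3% of the mutant reads. Levels are given as normalized read counts, mean ± SD of the 2 libraries of a group (n = 2), and changes as log2 changes ± SE with limma's Benjamini-Hochberg adjusted p. The labels do not state that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

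The transcript of pmk-3 itself was present in every library: 404 and 553 in non-BAG cells, 671 and 585 in wild-type BAG neurons and 259.8 and 284 in mutant BAG neurons. Both mutant libraries lay under all 4 wild-type libraries. The value against wild-type BAG neurons was -1.2 ± 0.28 and did not pass the threshold (limma adjusted p = 0.0784). For pmk-3 the limma call was gained without non-BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0326 and 0.0306). Over 18 alternatives pmk-3 passed in 5, with an adjusted p (limma, edgeR or DESeq2) of 0.0184 to 0.533. What the wz31 mutation removes is not given in the sources used here, so the level of the transcript checks the labels only in part. The insulin-like peptide gene ins-1, the class of signal named by the series title, stood at 26 and 25.4 in non-BAG cells, 1972 and 579.6 in wild-type BAG neurons, and 2121 and 2571 in mutant BAG neurons. It rose in wild-type BAG over non-BAG cells by 5.33 ± 0.48 (limma adjusted p = 0.000114). In mutant over wild-type BAG neurons its value of 1.13 ± 0.48 did not pass (limma adjusted p = 0.296), and was 2.01 without wild-type BAG replicate 1 and 0.24 without wild-type BAG replicate 2.

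**Figure D1:**
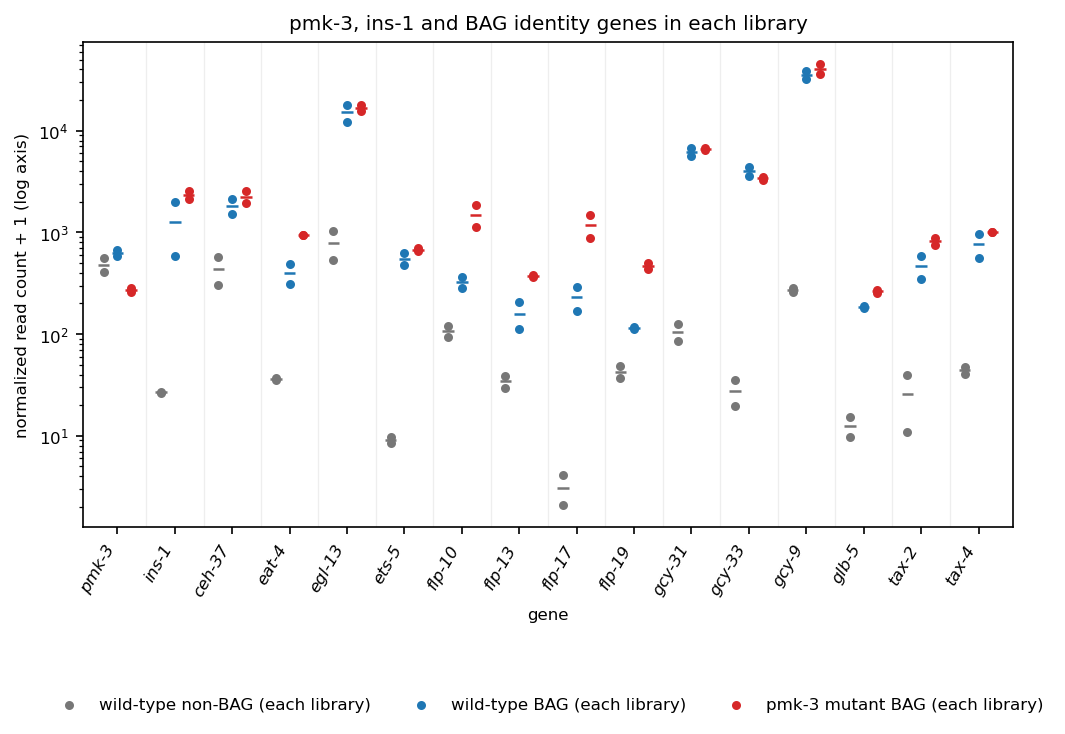
Normalized read count plus 1 (log axis) of pmk-3, ins-1 and the 14 BAG identity genes in each of the 6 libraries, with 1 point per library, a line at the group mean and the groups in different colours. The BAG identity genes stand above the non-BAG libraries in both BAG groups, and pmk-3 stands at 259.8 and 284 in the mutant.

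The first comparison, wild-type BAG against wild-type non-BAG cells, shows which transcripts mark the sorted neuron. All 14 genes of the BAG identity list rose, with a median change of 4.19 (14 adjusted over the list alone). The BAG identity list had camera adjusted p = 5.50e-18, and adjusted p = 0.124 with an estimated correlation. The receptor guanylyl cyclase gene gcy-9, whose promoter set the sorting gate, reached 35310.5 ± 4533 against 269.5 ± 15.1, a rise of 7.02 ± 0.28. The soluble guanylyl cyclase genes gcy-33 and gcy-31, which act in oxygen sensing, rose by 7.26 ± 0.32 and 5.92 ± 0.28. The transcription factor genes ets-5, egl-13 and ceh-37 rose by 5.9 ± 0.31, 4.31 ± 0.36 and 2.11 ± 0.35. The cyclic nucleotide-gated channel genes tax-2 and tax-4 rose by 4.43 ± 0.54 and 4.07 ± 0.32, the vesicular glutamate transporter gene eat-4 by 3.43 ± 0.31 and the globin gene glb-5 by 3.92 ± 0.37. The FMRFamide-like peptide gene flp-17 stood at 229 ± 88 against 2.09 ± 1.43, and flp-13, flp-10 and flp-19 rose by 2.16 ± 0.38, 1.61 ± 0.33 and 1.44 ± 0.32. For flp-10 the limma call was lost without wild-type BAG replicate 2 (adjusted p = 0.0635). For flp-19 the limma call was lost without wild-type BAG replicate 1, wild-type BAG replicate 2, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.0629, 0.0722, 0.0521 and 0.0528). The exons of ets-5 overlap those of cal-5 on the same strand, and those of eat-4 and flp-19 overlap ZK512.2 and the more abundant abl-1 on the other strand; no use of strand in the counting is stated, so these levels are uncertain.

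Outside that list, the globin genes Y57G11B.97 (now glb-34) and glb-7 rose by 7.68 ± 0.28 and 6.43 ± 0.54, and the homeobox gene ceh-54 by 7.15 ± 0.30. Among genes with a mean of at least 100.0 over the 6 libraries, other large rises were those of the uncharacterized genes C04E6.13 (7.39 ± 0.40) and Y48G8AR.2 (6.44 ± 0.35), the metabotropic glutamate receptor gene mgl-3 (6.47 ± 0.30), the neuropeptide genes F14F11.2 (now nlp-55) (7.0 ± 0.66) and nlp-1 (6.6 ± 0.49), and lin-15A (6.51 ± 0.31), a gene of the synthetic multivulva class. C04E6.4 stood at 163 ± 28.7 in BAG neurons and had a single read in the non-BAG libraries, so no fold is given. The limma adjusted p of these rises lay between 3.93e-06 and 0.000133. Exons of lin-15A overlap those of lin-15B on the same strand, and whether the counting split their reads is not given. Large falls at a mean of at least 100.0 were ZC116.3 (now cubn-1), by 5.44 on the log2 scale from 2463 ± 789.8 to 55.9 ± 19.1, the basement membrane gene nid-1 (-3.91 ± 0.42), the forkhead gene let-381 (-3.65 ± 0.46), pqn-62 (-3.47 ± 0.30), upb-1 (-3.44 ± 0.42) and the extracellular matrix gene mig-6 (-3.37 ± 0.31). Others were tmc-2 (-3.25 ± 0.33), F29B9.8 (-3.24 ± 0.38), nrf-5 (-3.11 ± 0.39), the muscle regulator gene pat-9 (-3.07 ± 0.41), spp-10 (-2.99 ± 0.35) and R02F2.2 (now osg-1) (-2.97 ± 0.38). The non-BAG level of let-381 is uncertain, since its exons overlap those of the more abundant F26B1.2 on the other strand and the counting is not stated to use strand. Limma adjusted p of these falls lay between 2.60e-05 and 0.000936. The level of glb-7 is uncertain too, since its exons overlap those of grl-20 on the other strand.

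Lists of peptide signalling genes were higher, except that of insulin-like peptides. Of the FLP neuropeptide genes 16 rose and 0 fell of 30 tested members (19 and 1 adjusted over the list alone), among them flp-16 (4.7 ± 0.38) and flp-25 (3.8 ± 0.47). The FLP neuropeptides list had camera adjusted p = 1.29e-08, and adjusted p = 0.169 with an estimated correlation. Of the NLP neuropeptide genes 25 of 62 tested members rose (28 adjusted over the list alone), with nlp-13 at 5.0 ± 0.35 and nlp-41, whose exons overlap mog-4, at 33.2 ± 7.33 against 0 ± 0. The NLP neuropeptides list had camera adjusted p = 9.63e-09, and adjusted p = 0.138 with an estimated correlation. In the list of peptide processing and dense-core vesicles 12 rose and 0 fell of 18 tested members (13 and 1 adjusted over the list alone), including the convertase genes aex-5 (5.23 ± 0.31) and egl-3 (4.05 ± 0.35), the carboxypeptidase gene egl-21 (3.35 ± 0.27) and the exocytosis gene unc-31 (3.35 ± 0.24). The peptide processing and dense-core vesicles list had camera adjusted p = 1.45e-09, and adjusted p = 0.213 with an estimated correlation. Among neuropeptide receptor genes 26 rose and 4 fell of 84 tested members (30 and 5 adjusted over the list alone), led by npr-7 (6.21 ± 0.40) and npr-15 (4.71 ± 0.26); npr-9 (5.7 ± 0.38) overlaps gcy-9 on the other strand, so its level is uncertain. The neuropeptide GPCRs list had camera adjusted p = 4.37e-06, and adjusted p = 0.204 with an estimated correlation. Insulin-like peptide genes did not move as a list: 2 rose and 0 fell of 21 tested members (1 and 0 adjusted over the list alone), with a median of -0.37 and a mean of 0.06 (camera adjusted p = 1). The members that rose were ins-1 and daf-28 (1.91 ± 0.56, limma adjusted p = 0.0491). For daf-28 the limma call was lost without non-BAG replicate 1, non-BAG replicate 2, wild-type BAG replicate 1, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.0626, 0.0989, 0.267, 0.116 and 0.121). In the insulin signalling pathway list 3 of 15 tested members rose (3 adjusted over the list alone): the insulin receptor substrate gene ist-1 (4.47 ± 0.29), akt-2 (1.73 ± 0.28) and the 14-3-3 gene par-5 (1.66 ± 0.29). The insulin signalling pathway list had camera adjusted p = 0.0125, and adjusted p = 0.478 with an estimated correlation. Exons of aex-5 overlap those of the equally abundant F32A7.5 on the other strand, and those of flp-16 overlap rmo-1, so the levels of aex-5 and flp-16 are uncertain. Insulin-like peptides had a median of -0.37, and of 0.013 and 0.28 without non-BAG replicate 2 and wild-type BAG replicate 2.

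Most lists of neuronal and sensory genes were higher as well. Of pan-neuronal genes 15 of 20 tested members rose (19 adjusted over the list alone), with the synaptotagmin gene snt-1 at 4.42 ± 0.25 and rab-3 at 3.72 ± 0.28. The pan-neuronal list had camera adjusted p = 1.14e-15, and adjusted p = 0.169 with an estimated correlation. Of synaptic vesicle release genes 22 of 31 tested members rose (27 adjusted over the list alone), with unc-41 at 3.47 ± 0.28 and ric-4 at 3.37 ± 0.25. The synaptic vesicle list had camera adjusted p = 1.49e-18, and adjusted p = 0.138 with an estimated correlation. Of genes for cilia and intraflagellar transport 44 rose and 1 fell of 55 tested members (49 and 2 adjusted over the list alone), led by mks-2 (3.88 ± 0.44) and dyf-18 (3.84 ± 0.39). The cilia and intraflagellar transport list had camera adjusted p = 2.92e-21, and adjusted p = 0.265 with an estimated correlation. In the cGMP signalling list 13 of 39 tested members rose (15 adjusted over the list alone), with the phosphodiesterase gene pde-1 at 5.19 ± 0.26, and in the list of guanylyl cyclases 7 of 29 tested members rose (7 adjusted over the list alone), with gcy-12 at 3.27 ± 0.34. For cGMP signalling and receptor and soluble guanylyl cyclases camera gave adjusted p = 1.12e-05 and 0.00464, and adjusted p = 0.138 and 0.169 with an estimated correlation. In the lists of channels and G proteins 23 rose and 3 fell of 64 tested members (25 and 5 adjusted over the list alone) among potassium and calcium channels, led by exp-2 (4.26 ± 0.26) and egl-36 (3.62 ± 0.42), and 11 rose and 0 fell of 39 tested members (14 and 0 adjusted over the list alone) among G proteins and regulators, led by grk-2 (3.41 ± 0.24) and rgs-6 (3.22 ± 0.25). For potassium and calcium channels and G proteins and regulators camera gave adjusted p = 0.000133 and 4.87e-05, and adjusted p = 0.169 and 0.414 with an estimated correlation. Of the p38 PMK-3 and DLK-1 pathway 2 of 22 tested members rose (2 adjusted over the list alone), the kinase genes mkk-4 (1.63 ± 0.29) and dlk-1 (1.02 ± 0.26), while the list did not pass (camera adjusted p = 0.0567) and pmk-3 stood at 0.41 ± 0.28 (limma adjusted p = 0.385). For dlk-1 the limma call was lost without non-BAG replicate 2, wild-type BAG replicate 1, wild-type BAG replicate 2, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.0611, 0.155, 0.0635, 0.0806 and 0.0813). For the PMK-3 and DLK-1 pathway the camera call was gained, as higher, without wild-type BAG replicate 2 and non-BAG replicate 1 (adjusted p = 0.0204 and 0.0134, median 0.50 and 0.46). The level of egl-36 is uncertain, since its exons overlap those of the equally abundant R07A4.2 on the other strand. Receptor and soluble guanylyl cyclases had a median of 0.63, and of 0.36 without wild-type BAG replicate 1. G proteins and regulators had a median of 0.77, and of 1.21 without non-BAG replicate 1. The PMK-3 and DLK-1 pathway had a median of 0.41, and of 0.25 without non-BAG replicate 2.

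Lists that mark other cells, or cell division, were lower or did not pass, except that of monoamine neurons. Of body wall muscle markers 1 rose and 20 fell of 22 tested members (1 and 20 adjusted over the list alone): tni-3, pat-10 and the myogenic factor gene hlh-1 fell by 4.04, 2.52 and 2.5 on the log2 scale, and the member that rose was the myosin gene unc-54 (2.35 ± 0.31), at 34735 ± 2096 against 6840.0 ± 562. The body wall muscle markers had camera adjusted p = 2.15e-14, and adjusted p = 0.213 with an estimated correlation. Of cell cycle genes 17 of 29 tested members fell (23 adjusted over the list alone), with the kinetochore gene knl-1 at -1.9 ± 0.32 and the Aurora kinase gene air-2 at -1.86 ± 0.49. The cell cycle list had camera adjusted p = 1.59e-11, and adjusted p = 0.213 with an estimated correlation. Of histone genes 3 rose and 19 fell of 41 tested members (4 and 28 adjusted over the list alone); his-68 and his-40 changed by -2.36 ± 0.65 and -1.96 ± 0.26 and his-35 by 1.86 ± 0.25, and near-identical copies make single histone genes uncertain. The histones list had camera adjusted p = 4.48e-09, and adjusted p = 0.251 with an estimated correlation. Of coelomocyte and excretory markers 0 rose and 4 fell of 11 tested members (1 and 7 adjusted over the list alone), with cup-4 at -3.47 ± 0.61 and lgc-26 at -2.84 ± 0.72. The coelomocyte and excretory markers had camera adjusted p = 0.00209, and adjusted p = 0.169 with an estimated correlation. Cytosolic ribosomal protein genes had a median of -0.43, with none of 80 past the threshold. The cytosolic ribosomal proteins list had camera adjusted p = 9.06e-07, and adjusted p = 0.656 with an estimated correlation. Adjusted over the list alone none passed either, and the unadjusted p was under 0.05 for 4. Markers of pharynx, hypodermis, intestine, germline and glia did not pass as lists (camera adjusted p = 0.0964, 0.0686, 0.862, 0.0978 and 0.31). In the order given, 14, 20, 7, 16 and 17 members were tested. By limma 1, 0, 0, 0 and 2 rose and 0, 1, 0, 0 and 2 fell (1, 0, 0, 0 and 2 rose and 0, 0, 0, 0 and 3 fell adjusted over the list alone), and the unadjusted p was under 0.05 for 1, 3, 1, 2 and 6. Among markers of other neurons, 4 rose and 1 fell of 8 tested members (4 and 1 adjusted over the list alone) in the cholinergic list, led by acr-2 (3.77 ± 0.69), cho-1 (3.13 ± 0.50) and unc-17 (2.94 ± 0.38), with camera adjusted p = 0.0809. The monoamine list was higher, with 1 of 9 members past the threshold, cat-1 (1.57 ± 0.39), and 1 adjusted over the list alone. The monoamine neuron markers had camera adjusted p = 0.0405, and adjusted p = 0.465 with an estimated correlation. Lists for GABA neurons, touch neurons, oxygen-sensing neurons and other amphid neurons did not pass (camera adjusted p = 0.917, 0.462, 0.862 and 0.862), although mec-2 (3.76 ± 0.28) and gcy-37 (3.1 ± 0.34) rose and the touch neuron regulator gene mec-3, held by the touch and oxygen-sensing lists, fell (-2.08 ± 0.59). In these lists 5, 8, 10 and 19 members were tested. By limma 1, 2, 1 and 1 rose and 0, 1, 1 and 0 fell (2, 2, 1 and 0 rose and 1, 3, 1 and 0 fell adjusted over the list alone), and the unadjusted p was under 0.05 for 4, 5, 2 and 1. For hlh-1 the limma call was lost without non-BAG replicate 1 and wild-type BAG replicate 2 (adjusted p = 0.0689 and 0.0562). For air-2 the limma call was lost without non-BAG replicate 1, wild-type BAG replicate 2, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.155, 0.165, 0.0782 and 0.0788). For his-68 the limma call was lost without non-BAG replicate 2, wild-type BAG replicate 1, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.128, 0.193, 0.0792 and 0.0788). For lgc-26 the limma call was lost without non-BAG replicate 1 and wild-type BAG replicate 1 (adjusted p = 0.18 and 0.13). For cat-1 the limma call was lost without non-BAG replicate 1, wild-type BAG replicate 1, wild-type BAG replicate 2, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.0859, 0.136, 0.0806, 0.0673 and 0.0651). For mec-3 the limma call was lost without non-BAG replicate 1, non-BAG replicate 2, wild-type BAG replicate 1, wild-type BAG replicate 2, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.149, 0.134, 0.152, 0.099, 0.0759 and 0.0787). For pharynx markers the camera call was gained, as higher, without wild-type BAG replicate 1 (adjusted p = 0.00303, median 1.58). For monoamine neuron markers the camera call was lost without wild-type BAG replicate 1 and non-BAG replicate 1 (adjusted p = 0.0852 and 0.246). For hypodermis markers the camera call was gained, as lower, without wild-type BAG replicate 2 and non-BAG replicate 2 (adjusted p = 0.00709 and 0.00312, median -0.59 and -0.69). For germline markers the camera call was gained, as lower, without wild-type BAG replicate 2 and non-BAG replicate 1 (adjusted p = 0.0186 and 0.0169, median -1.07 and -1.0). For cholinergic neuron markers the camera call was gained, as higher, without wild-type BAG replicate 2 and non-BAG replicate 1 (adjusted p = 0.0465 and 0.0413, median 2.25 and 1.73). The GABA list had a mean of 0.11, and quantile normalization took the median of the amphid list from 0.066 to -0.000682. Because unc-17 and cha-1 share exons, and hlh-1 and the less abundant B0304.4 overlap in exons, the levels of unc-17 and hlh-1 are uncertain. Cytosolic ribosomal proteins had a median of -0.43, and of -0.18 and -0.69 without wild-type BAG replicates 1 and 2. Pharynx markers had a median of 0.83, and of 1.36, 1.58 and 0.14 without non-BAG replicate 2 and wild-type BAG replicates 1 and 2. Hypodermis markers had a median of -0.54, and of -0.089 and -0.34 without non-BAG replicate 1 and wild-type BAG replicate 1. Intestine markers had a median of -0.44, and of 0.11, -0.71 and -0.080 without non-BAG replicate 2 and wild-type BAG replicates 1 and 2. Germline markers had a median of -0.88, and of -0.42 and -0.58 without non-BAG replicate 2 and wild-type BAG replicate 1. Glia markers had a median of -0.45, and of -0.89 without non-BAG replicate 1. Monoamine neuron markers had a median of 1.37, and of 0.53 and 0.85 without non-BAG replicate 1 and wild-type BAG replicate 1. GABA neuron markers had a median of -0.72, and of -0.38, 0.90 and 0.32 without non-BAG replicates 1 and 2 and wild-type BAG replicate 1. The touch neuron list had a median of -1.04, and of -0.64 without non-BAG replicate 1. The oxygen-sensing list had a median of -0.14, and of 0.12, -0.44, -0.58 and 0.30 without non-BAG replicates 1 and 2 and wild-type BAG replicates 1 and 2. The amphid list had a median of 0.066, and of 0.27, 0.032, 5.42e-05 and 0.59 without non-BAG replicates 1 and 2 and wild-type BAG replicates 1 and 2.

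**Figure D2:**
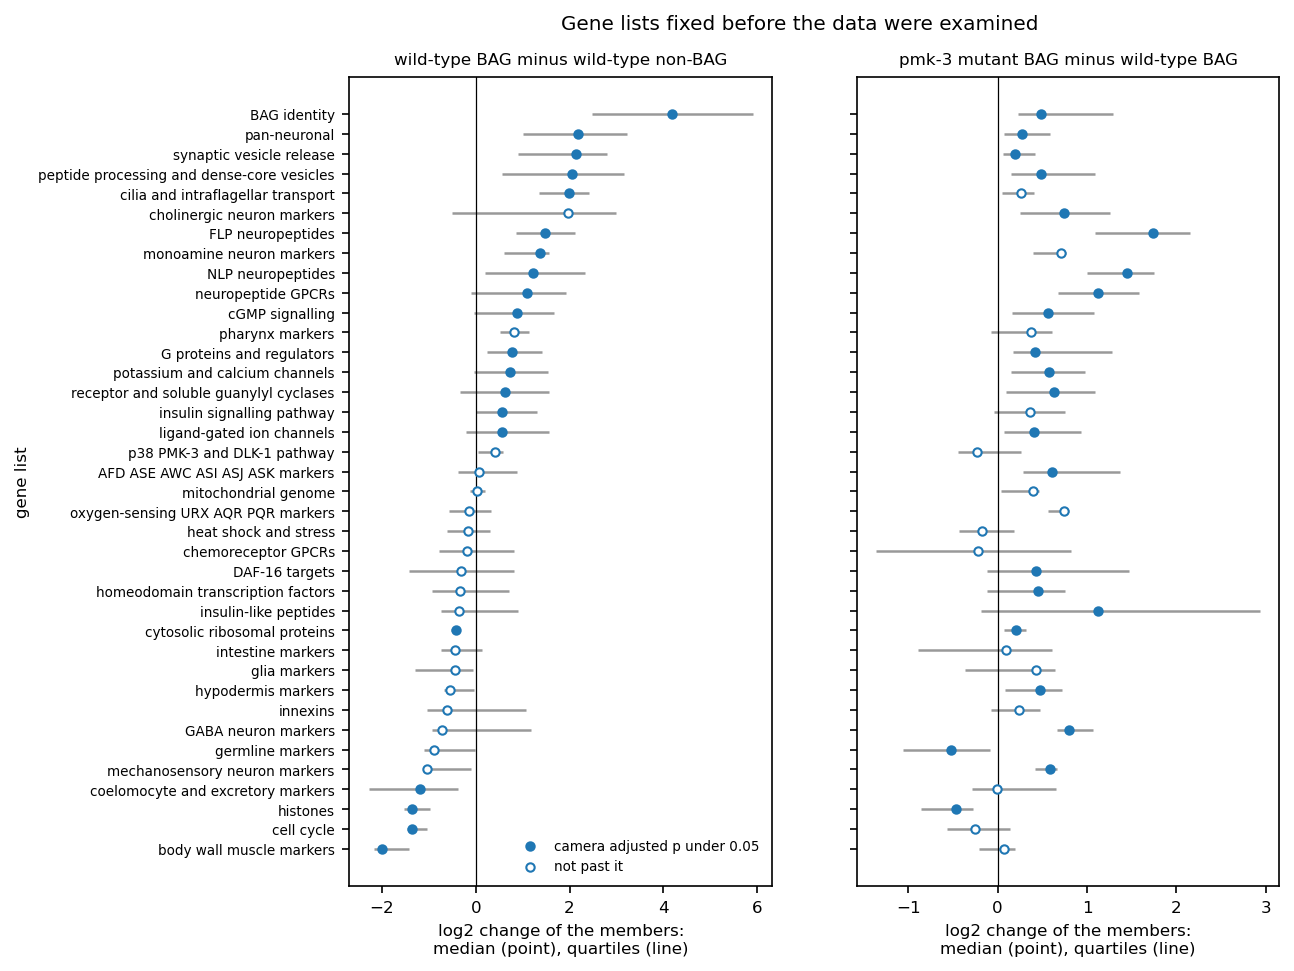
Median (point) and quartiles (line) of the log2 changes of the tested members of each of 38 gene lists, in wild-type BAG minus wild-type non-BAG (left) and pmk-3 mutant BAG minus wild-type BAG (right), with filled points for camera adjusted p under 0.05. On the left the BAG identity list has the highest median (4.19) and body wall muscle markers the lowest (-1.99); on the right the FLP and NLP neuropeptide lists have medians of 1.73 and 1.45.

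In all, 1444 genes rose and 570 fell in wild-type BAG against non-BAG cells among 14211 tested (limma, adjusted p under 0.05), and 15 lists were higher and 5 lower of 38 by camera, none of which held with an estimated correlation. The groups' values did not overlap for 53.6% of genes, where chance gives 33.3%. The counts rest on the libraries: 872 rose and 362 fell without wild-type BAG replicate 1, 988 rose and 325 fell without wild-type BAG replicate 2 and 1329 rose and 266 fell without non-BAG replicate 1, and the falls were 333 and 336 without mutant replicates 1 and 2, which enter the shared estimate of the spread. TMM scaling of the same values moved the median change of all genes from -0.038 to 0.0742. With only the groups compared 938 rose and 323 fell, and without trend 367 fell.

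The second comparison, pmk-3 mutant against wild-type BAG neurons, addresses what the kinase does to the transcripts of the developing neuron. Lists of neuropeptide genes were higher in the mutant. Of the NLP genes 7 of 62 tested members rose (30 adjusted over the list alone) and the median change was 1.45. The NLP neuropeptides list had camera adjusted p = 1.51e-20, and adjusted p = 0.109 with an estimated correlation. Of the FLP genes 4 rose and 1 fell of 30 tested members (23 and 1 adjusted over the list alone), with a median of 1.73. The FLP neuropeptides list had camera adjusted p = 2.35e-14, and adjusted p = 0.166 with an estimated correlation. The rises included nlp-18 (2.72 ± 0.36), F02D8.5 (now nlp-59) (2.52 ± 0.30), nlp-17 (2.52 ± 0.45), nlp-3 (2.04 ± 0.34), flp-6 (2.8 ± 0.42) and flp-14 (2.3 ± 0.41), whereas flp-25 fell by 3.67 on the log2 scale, from 1899 ± 1331 to 131 ± 34.1. Of insulin-like peptide genes 1 of 21 tested members rose (8 adjusted over the list alone), ins-30 (3.5 ± 0.55, 115 ± 47 against 9.17 ± 3.83), and the list had a median of 1.13. The insulin-like peptides list had camera adjusted p = 0.000374, and adjusted p = 0.191 with an estimated correlation. Among neuropeptide receptor genes 2 of 84 tested members rose (17 adjusted over the list alone), tag-89 (3.45 ± 0.58) and npr-15 (1.62 ± 0.26), with a median of 1.12. The neuropeptide GPCRs list had camera adjusted p = 2.29e-15, and adjusted p = 0.166 with an estimated correlation. In the list of peptide processing and dense-core vesicles 2 rose and 0 fell of 18 tested members (8 and 1 adjusted over the list alone): egl-21 (1.51 ± 0.27) and the amidating lyase gene pgal-1 (2.0 ± 0.32), the latter overlapping F21F3.6 on the other strand. The peptide processing and dense-core vesicles list had camera adjusted p = 0.000506, and adjusted p = 0.422 with an estimated correlation. None of these calls passed without wild-type BAG replicate 2 or mutant replicate 1 (lowest limma adjusted p = 0.0635 and 0.128). Those that passed with another BAG library left out were F02D8.5 and flp-25 without wild-type BAG replicate 1, and none without mutant replicate 2. The exons of nlp-17 likewise overlap those of seld-1 on the other strand, so the levels of pgal-1 and nlp-17 are uncertain. Peptide processing and dense-core vesicles had a median of 0.49, and of 0.83 and 0.32 without wild-type BAG replicates 1 and 2.

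Within the BAG identity list 2 of 14 tested members rose (5 adjusted over the list alone), both peptide genes, flp-10 (2.17 ± 0.33, limma adjusted p = 0.0275) and flp-19 (2.03 ± 0.32, limma adjusted p = 0.0301). The exons of flp-19 overlap those of the more abundant abl-1 on the other strand, so its level is uncertain. The list had a median of 0.49. The BAG identity list had camera adjusted p = 0.000154, and adjusted p = 0.19 with an estimated correlation. The value of flp-17 was 2.36 ± 0.47, from 229 ± 88 to 1174 ± 413, and missed the threshold (limma adjusted p = 0.0567). Sensory and regulatory members did not pass: gcy-9 stood at 0.20 ± 0.28, gcy-31 at 0.094 ± 0.28, gcy-33 at -0.24 ± 0.32, ets-5 at 0.32 ± 0.31, egl-13 at 0.17 ± 0.36, ceh-37 at 0.30 ± 0.35, tax-4 at 0.46 ± 0.32 and tax-2 at 0.85 ± 0.54. The values of eat-4, flp-13 and glb-5 were 1.29 ± 0.31, 1.29 ± 0.38 and 0.52 ± 0.37, with limma adjusted p = 0.0868, 0.14 and 0.535. None of the calls of flp-10 and flp-19 passed without wild-type BAG replicate 2, mutant replicate 1, wild-type BAG replicate 1 or mutant replicate 2 (in the first and second of these fits the lowest limma adjusted p = 0.091 and 0.166). For flp-17 the limma call was gained without non-BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0122 and 0.00995). For eat-4 the limma call was gained without non-BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0451 and 0.0399). Over 18 alternatives flp-17, eat-4 and flp-13 passed in 9, 5 and 1, with an adjusted p (limma, edgeR or DESeq2) of 1.34e-06 to 0.533, 0.00896 to 0.549 and 0.0485 to 0.61, respectively. The sign of gcy-9 turned with quantile normalization (-0.077), as did that of egl-13 (-0.087). Without wild-type BAG replicate 2 egl-13 and gcy-31 stood at -0.099 and -0.040.

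At a mean of at least 100.0, other large rises were B0294.1 (6.07 ± 0.99, from 7.48 ± 6.7 to 564 ± 434), F41B4.2 (3.59 ± 0.46), the leucine-rich repeat gene lron-12 (3.12 ± 0.28, from 132 ± 5.86 to 1161 ± 177), the acyl-CoA dehydrogenase gene acdh-2 (3.1 ± 0.55), D2092.1 (now mctp-1) (2.91 ± 0.43) and the TGF-β ligand gene daf-7 (2.83 ± 0.33, from 110.1 ± 14.9 to 804 ± 242). Others were the linker histone gene hil-1 (2.76 ± 0.46), srap-1 (2.74 ± 0.38), the sulfatase gene sul-2 (2.74 ± 0.41) and the nuclear receptor gene nhr-277 (2.69 ± 0.42). At that minimum mean, large falls were B0205.13 (-5.41 ± 0.84), the ABC transporter gene pgp-9 (-5.15 ± 0.46, from 260.4 ± 16.8 to 6.76 ± 3.46) and the beta-tubulin gene tbb-6 (-5.01 ± 0.53, from 725 ± 357 to 21.5 ± 10.8). Next came C52A10.1 (now cest-32) (-3.74 ± 0.35), F09F7.5 (-3.68 ± 0.44), F53B2.8 (-3.57 ± 0.43), drh-2 (-3.26 ± 0.40), which resembles an RNA helicase, the soluble guanylyl cyclase gene gcy-37 (-3.26 ± 0.34, from 752 ± 105 to 79 ± 24.9), K09F6.9 (-3.23 ± 0.41), phf-33 (-3.08 ± 0.49) and T09F5.12 (-3.08 ± 0.56). In the p38 PMK-3 and DLK-1 pathway the MAP kinase kinase gene sek-3 fell by 1.53 on the log2 scale, 1 of 22 members past the threshold (3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.166). For the PMK-3 and DLK-1 pathway the camera call was gained, as lower, without wild-type BAG replicate 2 (adjusted p = 0.0386, median -0.25). None of these calls passed without wild-type BAG replicate 2 or mutant replicate 1 (lowest limma adjusted p = 0.0539 and 0.112). Those that passed with another BAG library left out were lron-12, pgp-9, tbb-6, C52A10.1 and F09F7.5 without wild-type BAG replicate 1 and B0205.13 and pgp-9 without mutant replicate 2. The level of C52A10.1 is uncertain, since its exons overlap Y49G5B.1 on the other strand. The PMK-3 and DLK-1 pathway had a median of -0.23, and of -0.068 and -0.067 without wild-type BAG replicate 1 and mutant replicate 2.

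**Figure D3:**
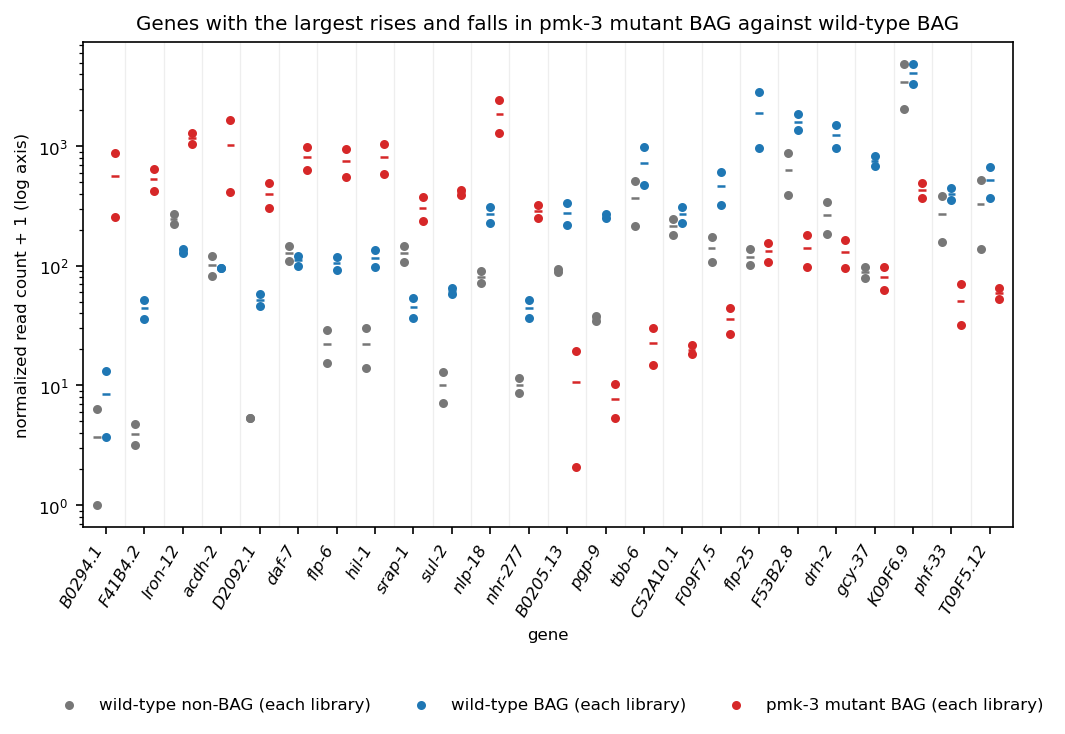
Normalized read count plus 1 (log axis) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) in mutant against wild-type BAG neurons, with 1 point per library, a line at the group mean and the 3 groups in different colours. Only genes with a mean of at least 100.0 and no overlap between the groups were ranked. Among them the largest rise is that of B0294.1 (6.07 on the log2 scale) and the largest fall that of B0205.13 (-5.41). The fitted change is on the log2(value + 1) scale.

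Markers of other neurons were higher as lists in the mutant by small medians: cholinergic (0.75), GABA (0.79), touch (0.59) and amphid neurons (0.61), with daf-7 as their 1 member past the threshold. For cholinergic neuron markers, GABA neuron markers, touch neuron and amphid camera gave adjusted p = 0.021, 0.0368, 0.03 and 0.0147, and adjusted p = 0.422, 0.422, 0.422 and 0.389 with an estimated correlation. In these lists 8, 5, 8 and 19 members were tested. By limma 0, 0, 0 and 1 rose and none fell (1, 0, 0 and 1 rose and none fell adjusted over the list alone), and the unadjusted p was under 0.05 for 3, 1, 1 and 5. The members named by the rule in the first 3 of these lists did not pass: unc-3 (0.31 ± 0.44), unc-17 (1.42 ± 0.38), snf-11 (0.79 ± 0.40), unc-25 (1.25 ± 0.59), mec-2 (0.57 ± 0.28) and mec-12 (0.65 ± 0.27). Without wild-type BAG replicate 2 unc-3 stood at -0.068. The monoamine and oxygen-sensing lists did not pass (camera adjusted p = 0.136 and 0.234), with gcy-37 as the member of the latter that fell. In this pair of lists 9 and 10 members were tested. By limma 0 and 1 fell and none rose (0 and 1 rose and 0 and 1 fell adjusted over the list alone), and the unadjusted p was under 0.05 for 0 and 3. Lists of pan-neuronal, synaptic vesicle, cGMP signalling, guanylyl cyclase, channel and G protein genes had medians of 0.27, 0.19, 0.56, 0.63, 0.58 and 0.42 and passed (camera adjusted p = 0.021, 0.021, 0.00218, 0.0192, 0.000113 and 9.08e-05). With an estimated correlation they did not (adjusted p = 0.565, 0.51, 0.19, 0.275, 0.19 and 0.422). In the order given, 20, 31, 39, 29, 64 and 39 members were tested. By limma 1, 0, 1, 0, 1 and 0 rose and 0, 0, 1, 1, 0 and 0 fell (2, 0, 3, 2, 7 and 7 rose and 0, 0, 1, 1, 2 and 0 fell adjusted over the list alone), and the unadjusted p was under 0.05 for 6, 4, 9, 7, 21 and 10. The members that passed were egl-21 and gcy-37, given above, and 2 others: the cGMP-dependent kinase gene pkg-2 (1.62 ± 0.29) and the potassium channel gene irk-3 (2.4 ± 0.42), which rose. Abundant members that did not pass were gpb-1 (0.41 ± 0.35), goa-1 (0.31 ± 0.32), cab-1 (1.65 ± 0.48) and snb-1 (-0.13 ± 0.26). Cilia genes did not pass (median 0.26, camera adjusted p = 0.0748), nor did body wall muscle markers (median 0.073, camera adjusted p = 0.872). For cilia and muscle 55 and 22 members were tested. By limma none rose or fell (none rose or fell adjusted over the list alone), and the unadjusted p was under 0.05 for 2 and 2. Body wall muscle markers had a mean of 0.017 and were lower by camera's sign. For the touch neuron list the camera call was lost without wild-type BAG replicate 1, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.132, 0.053 and 0.0718). For cilia and intraflagellar transport the camera call was gained, as higher, without wild-type BAG replicate 1 and mutant replicate 1 (adjusted p = 5.64e-06 and 0.0496, median 0.65 and 0.30). For the pan-neuronal list the camera call was lost without wild-type BAG replicate 2 and mutant replicate 1 (adjusted p = 0.18 and 0.0743). For the synaptic vesicle list the camera call was lost without wild-type BAG replicate 2 and mutant replicate 1 (adjusted p = 0.19 and 0.0767). For receptor and soluble guanylyl cyclases the camera call was lost without wild-type BAG replicate 2 and mutant replicate 1 (adjusted p = 0.0516 and 0.0939). For cholinergic neuron markers the camera call was lost without wild-type BAG replicate 2 and mutant replicate 1 (adjusted p = 0.141 and 0.184). For GABA neuron markers the camera call was lost without wild-type BAG replicate 2 and mutant replicate 1 (adjusted p = 0.165 and 0.177). For the amphid list the camera call was lost without wild-type BAG replicate 2 and mutant replicate 1 (adjusted p = 0.141 and 0.0976). The pan-neuronal list had a median of 0.27, and of 0.11 without wild-type BAG replicate 2. The synaptic vesicle list had a median of 0.19, and of 0.31 and 0.10 without wild-type BAG replicates 1 and 2. Cholinergic neuron markers had a median of 0.75, and of 0.39 without wild-type BAG replicate 2. GABA neuron markers had a median of 0.79, and of 1.3 without wild-type BAG replicate 1. The amphid list had a median of 0.61, and of 1.05, 0.17, 0.39 and 1.03 without wild-type BAG replicates 1 and 2 and mutant replicates 1 and 2. Monoamine neuron markers had a median of 0.71, and of 0.45 without wild-type BAG replicate 2. The oxygen-sensing list had a median of 0.74, and of 0.45 and 0.49 without wild-type BAG replicate 2 and mutant replicate 1. Cilia and intraflagellar transport had a median of 0.26, and of 0.65, -0.14 and 0.17 without wild-type BAG replicates 1 and 2 and mutant replicate 2. Body wall muscle markers had a median of 0.073, and of 0.14 and -0.097 without wild-type BAG replicates 1 and 2. None of the calls of daf-7, pkg-2 and irk-3 passed without wild-type BAG replicate 2, mutant replicate 1, wild-type BAG replicate 1 or mutant replicate 2 (in the first and second of these fits the lowest limma adjusted p = 0.0556 and 0.14). For unc-17 the limma call was gained without non-BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0421 and 0.0346). For cab-1 the limma call was gained without non-BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0115 and 0.00936). Over 18 alternatives unc-17 and cab-1 passed in 5 and 5, with an adjusted p (limma, edgeR or DESeq2) of 0.00983 to 0.544 and 0.00509 to 0.62, respectively.

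Histone genes and germline markers were lower as lists, with medians of -0.47 and -0.52 and 0 of 41 and 0 of 16 members past the threshold (his-6 -0.43 ± 0.29, his-72 -0.36 ± 0.27, spr-5 -0.94 ± 0.26, meg-2 -1.46 ± 0.41). For histones and germline markers camera gave adjusted p = 1.13e-05 and 0.00927, and adjusted p = 0.422 and 0.51 with an estimated correlation. Adjusted over the list alone 0 and 3 fell, and the unadjusted p was under 0.05 for 7 and 4 members. Hypodermis markers (median 0.47) and cytosolic ribosomal protein genes (median 0.21) were higher with none past it (fbn-1 0.0012 ± 0.41, noah-1 0.50 ± 0.31, rpl-18 0.41 ± 0.29, rpl-3 0.076 ± 0.28), and the exons of fbn-1 overlap those of upp-1 on the other strand, so its level is uncertain. For hypodermis markers and cytosolic ribosomal proteins camera gave adjusted p = 0.0202 and 0.0147, and adjusted p = 0.56 and 0.759 with an estimated correlation. Of their members 3 and 0 had an unadjusted p under 0.05 and none passed adjusted over the list alone. Without wild-type BAG replicate 1 fbn-1 and rpl-3 stood at -0.62 and -0.075, and fbn-1 stood at -0.14 without mutant replicate 1 and at -0.055 with TMM scaling. Pharynx, intestine, glia, coelomocyte and cell cycle lists did not pass (camera adjusted p = 0.633, 0.743, 0.306, 0.555 and 0.0555), nor did the insulin signalling pathway (camera adjusted p = 0.108). In the order given, 14, 7, 17, 11, 29 and 15 members were tested. By limma none rose or fell (0, 0, 0, 1, 0 and 1 rose and none fell adjusted over the list alone), and the unadjusted p was under 0.05 for 2, 1, 2, 3, 4 and 5. The intestine list had a median of 0.093 and a mean of -0.23, and the coelomocyte list had a median of -0.0058 and a mean of 0.18. For hypodermis markers the camera call was lost without wild-type BAG replicate 1 and mutant replicate 1 (adjusted p = 0.566 and 0.144). For cytosolic ribosomal proteins the camera call was lost without wild-type BAG replicate 1 and mutant replicate 2 (adjusted p = 0.455 and 0.532). For germline markers the camera call was lost without wild-type BAG replicate 2 (adjusted p = 0.154). For pharynx markers the camera call was gained, as higher, without wild-type BAG replicate 2 (adjusted p = 0.0291, median 0.58). For insulin signalling pathway the camera call was gained, as higher, without mutant replicate 1 (adjusted p = 0.0316, median 0.38). For cell cycle the camera call was gained, as lower, without mutant replicate 2, non-BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0379, 0.0485 and 0.0455, median -0.36, -0.25 and -0.25). Histones had a median of -0.47, and of -0.30 without wild-type BAG replicate 2. Germline markers had a median of -0.52, and of -0.98 and -0.30 without wild-type BAG replicate 1 and mutant replicate 1. Hypodermis markers had a median of 0.47, and of 0.23 and 0.28 without wild-type BAG replicate 1 and mutant replicate 1. Cytosolic ribosomal proteins had a median of 0.21, and of -0.036, 0.44, 0.34 and 0.079 without wild-type BAG replicates 1 and 2 and mutant replicates 1 and 2. Pharynx markers had a median of 0.37, and of -0.39 and 0.58 without wild-type BAG replicates 1 and 2. Intestine markers had a median of 0.093, and of -0.56, -0.13, 0.37 and -0.38 without wild-type BAG replicates 1 and 2 and mutant replicates 1 and 2. Glia markers had a median of 0.42, and of 0.24 without mutant replicate 2. Coelomocyte and excretory markers had a median of -0.0058, and of -0.35, 0.35, 0.21 and -0.080 without wild-type BAG replicates 1 and 2 and mutant replicates 1 and 2. Cell cycle had a median of -0.25, and of -0.14 without mutant replicate 1. Insulin signalling pathway had a median of 0.36, and of 0.19 without mutant replicate 2. For meg-2 the limma call was gained without non-BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0473 and 0.0437). Over 18 alternatives spr-5 and meg-2 passed in 1 and 5, with an adjusted p (limma, edgeR or DESeq2) of 0.0485 to 0.54 and 0.0238 to 0.62, respectively.

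In this comparison 69 genes rose and 50 fell (limma, adjusted p under 0.05), 2261 genes had an unadjusted p under 0.05, and values did not overlap for 50.2% of genes, where chance gives 33.3%. These calls need both libraries of each BAG group: 3 rose and 6 fell without wild-type BAG replicate 1, 0 rose and 0 fell without wild-type BAG replicate 2, 0 rose and 0 fell without mutant replicate 1 and 0 rose and 2 fell without mutant replicate 2, and no call named here was kept in all 4 of these fits, in which the unadjusted p was under 0.05 for 2214, 1458, 1434 and 1162 genes. Without non-BAG replicate 1 257 rose and 245 fell, and without non-BAG replicate 2 298 and 257, since those libraries enter the shared estimate of the spread. On recovered reads, edgeR with TMM scaling gave 118 rises and 42 falls, a share of rises of 73.8% against 58%. DESeq2 gave 377 and 312, limma with only the groups compared 374 and 282, limma without trend 0 and 1 (2158 with an unadjusted p under 0.05), and a pseudocount of 8 gave 148 rises. On the second principal component, which held 18.3% of the variance, wild-type BAG replicate 2 stood at -80.6 against -7.83 for replicate 1 and 28.1 and 28.1 for the mutant libraries, and the non-BAG libraries at 60.2 and -27.9. By camera 21 lists were higher and 2 lower of 38, none with an estimated correlation, and 13 were higher without mutant replicate 1. The mutant libraries were the shallower BAG libraries and held the larger shares of ribosomal RNA.

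The BAG-enriched genes, 1425 with a rise of at least 1 log2 unit in wild-type BAG over non-BAG cells, were followed into the mutant. Of them 29 rose (2.04%) and 20 fell (1.4%) in mutant against wild-type BAG neurons, against 40 (0.313%) and 30 (0.235%) of the 12786 other genes. Among those that rose were flp-10, flp-19 and npr-15, and among those that fell flp-25 and gcy-37. The set's median change was 0.37 against -0.023 for the others (camera p = 4.04e-08, and p = 0.0511 with an estimated correlation). At a rise of at least 2 log2 units the set held 944 genes, of which 21 rose and 14 fell, with a median of 0.44 (camera p = 1.54e-08, and p = 0.0323 with an estimated correlation), so whether the set passes with an estimated correlation rests on the cutoff. The same wild-type BAG libraries enter both comparisons: the change over genes correlated at 0.052 where unchanged groups gave -0.50 in 100 simulated sets, and the covariance was 0.0635 against -0.179, a difference of 0.243. Independent lists, with all 1444 genes that rose in BAG at any size of rise, would share 7.01 genes that rose in both, where 29 did, and 5.08 that rose in BAG and fell in the mutant, where 20 did. Of genes that fell in BAG, 3 rose in the mutant (independent lists 2.77) and 0 fell (independent lists 2.01). Unchanged groups gave opposite signs for 66.6% of genes, so the shared libraries may account for part of the excess of genes that rose in BAG and fell in the mutant. In sign they pull against a rise in both. Both comparisons also use the same fitted spread of each gene, which may make the same genes pass in both, in either direction. Neither the independent lists nor the simulated signs take this in, so they cannot decide what the excess of shared calls means. When the set was chosen with 1 wild-type BAG library and tested with the other, 1 rose and 2 fell of 988 with replicate 1 choosing, and 0 rose and 0 fell of 872 with replicate 2 choosing, fits in which 2214 and 1458 of all genes had an unadjusted p under 0.05. The medians were then 0.54 and 0.44 (camera p = 4.79e-13 and 5.50e-09, and p = 0.0554 and 0.105 with an estimated correlation).

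The third comparison set mutant BAG neurons against wild-type non-BAG cells, so that genotype and cell type differ together. All 14 BAG identity genes rose again (14 adjusted over the list alone; median 4.62), with flp-17 at 1174 ± 413 and gcy-9 at 40528 ± 6549, and ins-1 rose by 6.45 ± 0.48. The BAG identity list had camera adjusted p = 2.52e-16, and adjusted p = 0.0715 with an estimated correlation. Other large rises were C04E6.13 (8.63 ± 0.40), nlp-1 (8.29 ± 0.49), Y48G8AR.2 (7.78 ± 0.35), Y57G11B.97 (7.74 ± 0.28), B0294.1 (7.55 ± 0.99), F14F11.2 (7.54 ± 0.66), F49C5.4 (now nimk-1) (7.49 ± 0.55), npr-7 (7.32 ± 0.40), mgl-3 (7.28 ± 0.30) and F49C5.3 (7.18 ± 0.42). Large falls were ZC116.3 (-4.51 ± 0.37), nid-1 (-4.28 ± 0.42), E01G4.5 (-4.02 ± 0.35), tbb-6 (-3.98 ± 0.53), B0205.13 (-3.85 ± 0.84), nrf-5 (-3.78 ± 0.39), ugt-18 (-3.64 ± 0.59), ZK822.1 (-3.42 ± 0.32), C52A10.1 (-3.41 ± 0.35), let-381 (-3.39 ± 0.46), spp-10 (-3.36 ± 0.35) and his-68 (-3.35 ± 0.65). The genes tbb-6, B0205.13 and C52A10.1 also fell in mutant against wild-type BAG neurons, where both comparisons use the same mutant libraries.

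Against non-BAG cells, 26 of 30 tested members rose (27 adjusted over the list alone) among FLP genes and 44 of 62 tested members rose (49 adjusted over the list alone) among NLP genes. For FLP neuropeptides and NLP neuropeptides camera gave adjusted p = 2.03e-14 and 2.00e-18, and adjusted p = 0.0855 and 0.0715 with an estimated correlation. Of insulin-like peptide genes 9 rose and 0 fell of 21 tested members (11 and 1 adjusted over the list alone), among them daf-28 (4.42 ± 0.56). The insulin-like peptides list had camera adjusted p = 0.0326, and adjusted p = 0.259 with an estimated correlation. Of neuropeptide receptor genes 48 rose and 3 fell of 84 tested members (57 and 3 adjusted over the list alone), with npr-15 at 6.33 ± 0.26 and npr-34 at 6.02 ± 0.47. The neuropeptide GPCRs list had camera adjusted p = 8.28e-15, and adjusted p = 0.0855 with an estimated correlation. In the peptide processing list egl-3 stood at 26574 ± 6749 against 473 ± 204 (5.86 ± 0.35), and 13 rose and 1 fell of 18 tested members (13 and 1 adjusted over the list alone). The peptide processing and dense-core vesicles list had camera adjusted p = 6.19e-09, and adjusted p = 0.244 with an estimated correlation. Of cilia genes 47 rose and 1 fell of 55 tested members (48 and 1 adjusted over the list alone), and of body wall muscle markers 1 rose and 20 fell of 22 tested members (1 and 20 adjusted over the list alone), again with unc-54 as the member that rose (2.69 ± 0.31). For cilia and intraflagellar transport and body wall muscle markers camera gave adjusted p = 2.00e-18 and 8.92e-11, and adjusted p = 0.259 and 0.259 with an estimated correlation. Of histone genes 4 rose and 29 fell of 41 tested members (4 and 30 adjusted over the list alone), and of cell cycle genes 19 of 29 tested members fell (21 adjusted over the list alone), with cyb-3 at -2.59 ± 0.33. For histones and cell cycle camera gave adjusted p = 8.92e-11 and 2.09e-10, and adjusted p = 0.244 and 0.244 with an estimated correlation. The pmk-3 transcript stood at -0.80 ± 0.28 (limma adjusted p = 0.0626). In all 2300 genes rose and 1328 fell (limma, adjusted p under 0.05), and 1201 rose and 494 fell without mutant replicate 1 and 1070 rose and 302 fell without mutant replicate 2, with 869 falls without trend. By camera 17 lists were higher and 6 lower of 38, none with an estimated correlation. The groups' values did not overlap for 66.1% of genes, where chance gives 33.3%. For insulin-like peptides the camera call was lost without non-BAG replicate 1 (adjusted p = 0.0623). For pmk-3 the limma call was gained without non-BAG replicate 1 (adjusted p = 0.036). For his-68 the limma call was lost without mutant replicate 2 (adjusted p = 0.073). Over 18 alternatives pmk-3 passed in 3, with an adjusted p (limma, edgeR or DESeq2) of 0.036 to 0.258.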

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

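The tests of gene lists with 1 library left out were chosen after the result was seen. Calls of genes kept their direction in every alternative in which they were tested, and so did calls of lists, except that of ribosomal proteins in mutant against wild-type BAG (median -0.0362 without wild-type BAG replicate 1). Where counts moved, the cause was not tested, except that leaving out libraries or groups leaves fewer samples. For wild-type BAG against non-BAG, 872 to 1449 genes rose and 266 to 760 fell with 1 library left out, 938 rose and 323 fell with only the groups compared, and 367 fell without trend. For mutant against wild-type BAG the ranges were 0 to 298 and 0 to 257 (unadjusted p under 0.05 for 1458 genes without wild-type BAG replicate 2), with 0 and 1 without trend (2158 unadjusted), 374 and 282 with only the groups compared, 377 and 312 by DESeq2, and rises of 148 with a pseudocount of 8 and 118 by edgeR. For mutant BAG against non-BAG they were 1070 to 2294 and 302 to 1361, with 869 falls without trend. No list passed with an estimated correlation in any comparison. Nor did the BAG identity list against non-BAG, where its 14 members all rose, so this test had little power. For mutant against wild-type BAG, fry gave 7 higher and 0 lower, and 13 to 21 lists were higher with 1 library left out. Of BAG-enriched genes 1 and 0 rose and 2 and 0 fell in the mutant when the set was chosen and tested on different wild-type BAG libraries. The replicate letters were not taken to pair the samples (correlations of deviations 0.46, 0.00403 and 0.0458); with the replicate number as a block, falls were 1011 for wild-type BAG against non-BAG and 1999 for mutant BAG against non-BAG, and for mutant against wild-type BAG 342 rose and 343 fell. With the block camera lost the monoamine list (adjusted p = 0.0525) and gained the pharynx list (0.0393) in wild-type BAG against non-BAG, gained the cilia list (0.0498) in mutant against wild-type BAG, and in mutant BAG against non-BAG gained the amphid and pharynx lists (0.039 and 0.0278) and lost the coelomocyte list (0.0526). Quantile normalization moved the median change of all genes to -0.138 for wild-type BAG and -0.226 for mutant BAG against non-BAG. In mutant against wild-type BAG, the sign turned for egl-13 (-0.087 with quantile normalization, -0.099 to 0.45 with 1 library left out), fbn-1 (-0.055 with TMM scaling, -0.024 with quantile normalization, -0.080 with DESeq2, -0.62 to 0.62 with 1 library left out), gcy-31 (-0.040 to 0.23 with 1 library left out), gcy-9 (-0.077 with quantile normalization), rpl-3 (-0.075 to 0.23 with 1 library left out) and unc-3 (-0.068 to 0.70 with 1 library left out). On data simulated for this comparison, most changes of 1 log2 unit were not called. Whether depth or the spread between libraries sets that limit was not tested.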

Other observations

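Of the tests on 3 patterns below, those of muscle markers, transgene, sort purity, other neurons, chance placement and a single segment were chosen after the result was seen. Of innexin genes, which form gap junctions, 5 of 22 tested members rose (6 adjusted over the list alone) in wild-type BAG over non-BAG cells, led by che-7 (4.13 ± 0.27) and unc-7 (2.8 ± 0.33), while the list's median was -0.61 and its mean 0.10 (camera adjusted p = 0.985). Among chemoreceptor genes 12 rose and 2 fell of 193 tested members (11 and 0 adjusted over the list alone) (median -0.19, mean 0.089, camera adjusted p = 0.862); srd-15 stood at 149 ± 48.8 and at 0 in the non-BAG libraries, and srd-16 rose by 4.34 ± 0.85, a level made uncertain by the overlapping grd-9. Among homeodomain genes 9 rose and 12 fell of 84 tested members (11 and 14 adjusted over the list alone) (camera adjusted p = 0.186), with ceh-79 at 3.81 ± 0.66 and the posterior Hox genes mab-5 and egl-5 at -3.44 ± 0.45 and -2.73 ± 0.67. Among ligand-gated channel genes 16 rose and 5 fell of 84 tested members (20 and 8 adjusted over the list alone), with lgc-40 at 5.55 ± 0.32 and lgc-28 at -5.02 ± 0.82. The ligand-gated ion channels list had camera adjusted p = 0.00824, and adjusted p = 0.478 with an estimated correlation. Of DAF-16 targets 2 rose and 0 fell of 11 tested members (2 and 3 adjusted over the list alone) (camera adjusted p = 0.862): hil-1 (2.49 ± 0.46) and the glycolysis gene gpd-2 (1.75 ± 0.29), whose exons overlap those of mai-1 on the same strand, so that its level is uncertain. Heat shock genes (camera adjusted p = 0.708; hsp-12.3 -2.33 ± 0.56) and mitochondrial genome transcripts (camera adjusted p = 0.921, lower by camera's sign with a median of 0.028) did not pass, and of 4 Toll-like pathway genes ikb-1 fell (-1.79 ± 0.44), 1 adjusted over the list alone. For heat shock and mitochondrial genes 28 and 11 members were tested. By limma 1 and 0 fell and none rose (none rose or fell adjusted over the list alone), and the unadjusted p was under 0.05 for 2 and 0. For srd-16 the limma call was lost without wild-type BAG replicate 2 (adjusted p = 0.0741). For egl-5 the limma call was lost without non-BAG replicate 1, wild-type BAG replicate 1, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.0835, 0.104, 0.059 and 0.0618). For hsp-12.3 the limma call was lost without non-BAG replicate 2, wild-type BAG replicate 1 and wild-type BAG replicate 2 (adjusted p = 0.0725, 0.0685 and 0.0747). For ikb-1 the limma call was lost without non-BAG replicate 1, wild-type BAG replicate 2, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.103, 0.131, 0.0517 and 0.051). For homeodomain transcription factors the camera call was gained, as lower, without wild-type BAG replicate 1 and non-BAG replicate 2 (adjusted p = 0.0161 and 0.00863, median -0.49 and -0.72). For chemoreceptor GPCRs the camera call was gained, as lower, without non-BAG replicate 1 (adjusted p = 0.0465, median -0.80). For ligand-gated ion channels the camera call was lost without non-BAG replicate 1 (adjusted p = 0.0635). Innexins had a median of -0.61, and of -0.28 and -0.21 without non-BAG replicate 1 and wild-type BAG replicate 2. Chemoreceptor GPCRs had a median of -0.19, and of -0.80, 0.47, 0.47 and -0.57 without non-BAG replicates 1 and 2 and wild-type BAG replicates 1 and 2. Homeodomain transcription factors had a median of -0.33, and of -0.046, -0.72 and -0.043 without non-BAG replicates 1 and 2 and wild-type BAG replicate 2. Ligand-gated ion channels had a median of 0.55, and of 0.85 without non-BAG replicate 2. DAF-16 targets had a median of -0.32, and of -0.076, -0.57 and -0.16 without non-BAG replicates 1 and 2 and wild-type BAG replicate 2. Heat shock and stress had a median of -0.17, and of 0.21, -0.51 and 0.053 without non-BAG replicates 1 and 2 and wild-type BAG replicate 2. Mitochondrial transcripts had a median of 0.028, and of -0.26, 0.26, 0.57 and -0.49 without non-BAG replicates 1 and 2 and wild-type BAG replicates 1 and 2.

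In mutant over wild-type BAG neurons, homeodomain genes had a median of 0.46, ligand-gated channels of 0.40 and DAF-16 targets of 0.43, the last with hil-1 as its member past the threshold. For homeodomain transcription factors, ligand-gated ion channels and DAF-16 targets camera gave adjusted p = 0.00953, 0.00156 and 0.03, and adjusted p = 0.608, 0.422 and 0.422 with an estimated correlation. In these lists 84, 84 and 11 members were tested. By limma 0, 0 and 1 rose and none fell (0, 0 and 1 rose and none fell adjusted over the list alone), and the unadjusted p was under 0.05 for 8, 8 and 4. Innexins, chemoreceptors, heat shock genes and mitochondrial transcripts did not pass (camera adjusted p = 0.448, 0.3, 0.34 and 0.0568), though the chemoreceptor gene srv-6 rose (2.64 ± 0.42) and srz-85 fell (-2.99 ± 0.49), a level made uncertain by the overlapping B0205.14. In the order given, 22, 193, 28 and 11 members were tested. By limma 0, 1, 0 and 0 rose and 0, 1, 0 and 0 fell (0, 1, 0 and 1 rose and 0, 1, 0 and 0 fell adjusted over the list alone), and the unadjusted p was under 0.05 for 2, 47, 2 and 2. None of the 4 Toll-like pathway genes passed, with an unadjusted p under 0.05 for 0, a median of 0.023 and a mean of -0.25. For DAF-16 targets the camera call was lost without wild-type BAG replicate 1 and mutant replicate 2 (adjusted p = 0.079 and 0.0795). For chemoreceptor GPCRs the camera call was gained, as lower, without wild-type BAG replicate 1 (adjusted p = 0.00391, median -0.71). For homeodomain transcription factors the camera call was lost without wild-type BAG replicate 2 and mutant replicate 1 (adjusted p = 0.244 and 0.0976). For mitochondrial transcripts the camera call was gained, as higher, without wild-type BAG replicate 2 (adjusted p = 2.81e-05, median 0.79). For ligand-gated ion channels the camera call was lost without mutant replicate 1 (adjusted p = 0.108). Homeodomain transcription factors had a median of 0.46, and of 0.15 without wild-type BAG replicate 2. Ligand-gated ion channels had a median of 0.40, and of 0.66 without mutant replicate 2. DAF-16 targets had a median of 0.43, and of 0.90, 0.69 and 0.77 without wild-type BAG replicate 1 and mutant replicates 1 and 2. Chemoreceptor GPCRs had a median of -0.22, and of -0.71, 0.29, -0.39 and -0.040 without wild-type BAG replicates 1 and 2 and mutant replicates 1 and 2. Mitochondrial transcripts had a median of 0.39, and of -0.054 and 0.79 without wild-type BAG replicates 1 and 2. Innexins had a median of 0.24, and of 0.43, 0.017 and 0.10 without wild-type BAG replicates 1 and 2 and mutant replicate 1. Heat shock and stress had a median of -0.17, and of -0.051, -0.31 and -0.020 without wild-type BAG replicates 1 and 2 and mutant replicate 2. None of the calls of hil-1, srv-6 and srz-85 passed without wild-type BAG replicate 2, mutant replicate 1, wild-type BAG replicate 1 or mutant replicate 2 (in the first and second of these fits the lowest limma adjusted p = 0.091 and 0.166).

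Lin-15A, lin-15B and the myosin gene unc-54 were higher in wild-type BAG than in non-BAG cells. The other 21 body wall muscle markers had a median change of -2.02 (bootstrap interval over genes -2.17 to -1.73), against 2.35 for unc-54. This argues against muscle cells in the gate as the cause of the rise of unc-54. It does not show a gate free of muscle. The median log2 value of the whole muscle list was 8.6 and 8.42 in the wild-type BAG libraries and 10.6 and 10.3 in the non-BAG libraries. That all 3 genes lay above every other member of their groups is how they were noticed, so it tests nothing; the 15 other synthetic multivulva genes had a median of -0.35 and a highest value of 1.05 (lin-52). Transcripts or untranslated sequence carried by the reporter transgene are a candidate explanation that these values cannot decide, since what the transgene holds is not given in the sources used here. A biological rise of these genes in BAG neurons stays open and was not tested.

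The 113 neuropeptide genes tested had a median change of 1.44 in mutant over wild-type BAG neurons, and none of 10000 random sets matched on exonic length and mean value reached it (highest 0.30; the smallest share they can give is 0.01%), which argues against a shift of short genes. A purer sort would raise BAG genes of every kind, and the 10 BAG identity genes other than peptide genes had a median of 0.31 (interval 0.14 to 0.66, against 1.3 to 1.67 for the peptide genes), so a purer sort is unlikely as the whole cause, while a part of the change may come from it. Other sets cannot decide this, since they were chosen on libraries of the tested change: 130 genes at least 5 log2 units above non-BAG cells in mutant BAG, the set tested first, had a median of 1.06, and 52 chosen on wild-type BAG 0.35. Markers of other neuron classes had a median of 0.70 (0.55 to 0.79, 55 genes), so other neurons in the mutant gate cannot be told apart from a change in BAG neurons, since those markers may also be made by BAG neurons. A difference in peptide expression between wild-type and pmk-3(wz31) BAG neurons stays open, and its cause was not tested.

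Among the 50 genes that fell in mutant against wild-type BAG neurons, 8 pairs were neighbours on a chromosome. None of 10000 random sets of tested genes had as many (mean 0.179, highest 4; the smallest share they can give is 0.01%), and the 69 genes that rose held 3 pairs, reached by 0.42% of sets. Only 2 of the 8 pairs overlapped in reference exons, but the authors' annotation may differ. Shared reads stay open, as for mir-5548 and K09F6.9 on the same strand. The pairs lay on 4 chromosomes, against 1 segment that differs between the strains. Several such segments, or shared regulation of neighbours, may each account for the pairs and were not tested.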
